A study of Mus musculus with 2 samples.

How the data were processed

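Gene expression in single cells was measured in liver endothelial cells sorted as DAPI-negative, CD45-negative and CD31-positive. CD31 (Pecam1) marks endothelium, and CD45 (Ptprc) marks blood leukocytes. The cells came from 1 adult mouse heterozygous for the sphinx allele of Gimap5 (sph/+) and 1 homozygous adult mouse (sph/sph), both of C57BL/6 background. Each mouse gave 1 droplet library made with version v3 of the 10x Genomics 3' kit. Per the submitters' processing notes, reads were processed with Cell Ranger 3.0 against mm10, while the header of the matrix files names software version 3.1.0. The annotation release was not given in the sources used here. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, over 31053 genes. The deposited barcodes are those the authors kept as cells.

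With 1 mouse per genotype no test between genotypes was possible, and no p-value or standard error is given. Every difference describes these libraries, not the genotypes, and library and genotype cannot be told apart. Intervals are 95% exact Clopper-Pearson intervals for shares of cells and 95% exact Poisson intervals for counts. An interval for a ratio of levels is the exact binomial interval of the pooled count. They cover counting error only. A count of 0 was given the limit that 3 counts allow.

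A barcode was kept with at least 500 detected genes, at least 1000 UMIs and at most 15% of UMIs from mitochondrially encoded (mt-) genes. Doublets were scored with Scrublet in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 0% of barcodes in both libraries, so the fallback fixed in advance was used, which removes the highest scores at the expected rate. That rate was 10.5% in sph/+ and 13.1% in sph/sph, and tied scores brought the marked shares to 11.9% of 12643 and 14.2% of 14196 scored barcodes. Both libraries were clustered together without integration, because integration could remove a difference between genotypes. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen within libraries entered 30 principal components. Sex-linked, Gimap, mt-, ribosomal and immunoglobulin genes were kept out of the variable genes. A graph of 15 nearest neighbours weighted by shared neighbours was clustered with leidenalg 0.10.2 at resolution 1.0, with Python 3.11.15, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6 and scipy 1.17.1.

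Clusters were named from marker lists fixed before the data were examined. The name of a cluster rested on its 10 genes with the highest level relative to all other clusters, after 20 CPM were added to both (CPM, UMI counts scaled to a common library total), and on the markers detected in at least 25% of its cells. An endothelial cluster had at least 3 of 13 pan-endothelial markers detected and no other type leading its top genes. Liver sinusoidal endothelial cell-like (LSEC-like) clusters needed 9 of 12 LSEC markers, continuous vascular-like clusters 5 of 15 markers, and lymphatic-like clusters 4 of 7. For the LSEC-like and continuous vascular-like names, the share of the type's markers detected also had to exceed that of the other type. A type's markers among the top genes had to be at least as many as those of the other type and of cycling cells. Lymphatic-like clusters needed at least as many lymphatic as LSEC or continuous markers there. Cycling clusters needed 3 proliferation markers among their top genes. Endothelial clusters that met no full set of conditions stayed unnamed, such as the sph/sph cluster of 797 cells, with 8 LSEC and 5 continuous markers detected. These numbers of markers were set after the data had been opened. A naming step was also corrected after the clusters were seen, because a group of 18 sph/+ cells with mesothelial and fibroblast markers had first been named LSEC-like. Classes led by another type in cells that also carried endothelial markers are called marked, since they can be mixtures.

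The main comparison summed raw counts over all endothelial-like cells of each library, so that the genes that part endothelial clusters did not choose the cells. Sums were scaled to CPM by total UMIs. A gene was measured if it reached 20 CPM in either library. The log2 ratio was taken as sph/sph over sph/+ after 1 CPM was added to both. Genes at least 2-fold apart were counted. A planned comparison within LSEC-like cells, and within any named class with at least 200 cells in each library, could not be made because no class had that many cells in both. The named genes were fixed by a rule before the data were examined. The rule took the 12 measured genes with the highest and the 12 with the lowest log2 ratio, leaving out mt-, ribosomal, haemoglobin, immunoglobulin, sex-linked and unnamed genes and markers of non-endothelial cells. It added 13 genes whatever their values, and in each list the up to 4 measured members with the largest absolute log2 ratio. Other genes printed with a value were chosen after their values were seen.

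The gene lists, 25 in number, were also fixed in advance. They covered LSEC identity, continuous capillary, basement membrane and matrix, angiocrine factors, scavenging and lysosome, portal or arterial zone, central or venous zone, Notch, BMP and SMAD, Wnt, vasoactive factors, coagulation, inflammatory adhesion and chemokines, interferon response, antigen presentation, the GIMAP family, ceramide enzymes, cell cycle, endothelial transcription factors, pan-endothelial genes, dissociation and immediate early genes, hypoxia and glycolysis, oxidative stress and unfolded protein, cholesterol and fatty acid handling, and endothelial to mesenchymal genes. Members at least 1.5-fold higher or lower were counted. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on expression in 20 bins. The percentile describes a list against other genes of these libraries and is not a test between genotypes. Lists of 14 non-endothelial cell types were summed over the endothelial-like cells, as a measure of other cells and of free RNA. Lists of heart and adipose, brain, lung and kidney capillary genes were added after the values had been seen. Gene positions were taken from GENCODE M21.

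For shares of cells with a UMI, each cell was thinned at random to 2000 UMIs, and shallower cells were left out. The steps were tested on simulated data made from the sums over kept cells, with 6784 genes passing the floor. Of 50 genes given a true 1.5-fold difference, 0 passed 2-fold. Of 50 genes given 2-fold, 34.0% passed, and at 4-fold and 8-fold 100% of 50 passed. Of 6585 genes without a difference, 0 passed. Both simulated libraries were drawn from the sph/+ levels with Poisson noise only. Variation between mice, libraries or cell mixtures was not simulated, so these values speak to counting error alone. A list of 20 genes with a true log2 ratio of 1 gave a median of 1.00, and 7 of 200 random lists lay outside the middle 95% of percentiles.

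The results were recomputed under 13 alternatives fixed in advance. These were mt- limits of 10% and 25%, at least 1000 genes and 2000 UMIs, no doublet removal, resolutions of 0.5 and 2.0, and each library clustered alone. Further ones were TMM scaling with calcNormFactors of edgeR 4.0.16, cells weighted equally, gene floors of 5 and 50 CPM, no floor on list members, and 5 CPM added before the ratio. A planned median over clusters with at least 50 cells of each library could not be run, because 0 endothelial clusters had them. Another 5 alternatives were added after seeing the data. They left out the lymphatic-like cells, or these and the cycling cells, clustered without the endothelial list genes, named LSEC-like clusters from 6 of 12 markers, or kept hepatocyte-marked clusters with at least 10 pan-endothelial markers.

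For the tests in the closing section, central-vein-like cells were the endothelial-like clusters with Rspo3 and Wnt9b among their top genes, a definition settled after the clusters were seen, as was a wider comparison that counts unnamed clusters as capillary. The conditions that leave the tests of hilar tissue and of organ lists open were also added after their values were seen. The ratio of cell ratios used all such clusters, with 73 sph/+ and 231 sph/sph cells, and was given a 95% Woolf interval. List medians and gene levels used only the cluster with cells of both libraries, 39 in sph/+ and 231 in sph/sph. The remaining cluster, of 34 sph/+ and 0 sph/sph cells, was left out there. These medians were given 95% intervals from 1000 Poisson resamples. Counts of 0 were kept at 0 in these medians and resamples, so medians of lists with few sph/+ counts can be overstated.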

Results

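Single-cell transcriptomes of sorted liver endothelium were compared between 1 sph/+ mouse and 1 sph/sph mouse. Gimap5 encodes a GTPase of the immunity-associated protein family that is expressed in lymphocytes and endothelium, and the sphinx allele is a missense mutation. The sph/+ library held 13136 barcodes with 64460283 UMIs, a median of 4446 UMIs and 2150 genes per barcode. The sph/sph library held 16386 barcodes with 68983780 UMIs, a median of 3484 UMIs and 1713 genes. After filtering and doublet removal, 10807 sph/+ cells and 11218 sph/sph cells were kept, with medians of 4407 and 3907 UMIs. Endothelial-like cells made up 93.5% of kept cells in sph/+ (93.1 to 94.0) and 94.99% in sph/sph (94.6 to 95.4). Neither library has a replicate, so each value below is that of 1 mouse.

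The comparison asks how the liver endothelium of a Gimap5-mutant mouse differs from that of a heterozygous mouse. In the sph/sph library most transcripts that mark sinusoidal endothelium were lower, though not all were scarce, and most transcripts of continuous capillaries were higher. Among the genes with the lowest ratios, Fcgr2b, the inhibitory Fc receptor of sinusoidal cells, was at 2209 CPM (2195 to 2222) in sph/+ and 2.51 CPM (2.10 to 2.99) in sph/sph, 877-fold lower. Clec4g, a C-type lectin, was 61.7-fold lower, and Stab2, the hyaluronan scavenger receptor, was 33.9-fold lower. Gata4, the transcription factor that specifies sinusoidal endothelium, was at 270 CPM (265 to 275) and 31.3 CPM (29.8 to 32.8), 8.62-fold lower. Cd34, a marker of continuous endothelium, was 23.5-fold higher in sph/sph (22.2 to 24.8), and Cav1, the coat protein of caveolae, was 21.0-fold higher (20.1 to 22.0).

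Gimap5 itself, which lies on chromosome 6 from 48746197 to 48754210 in GRCm38 (ENSMUSG00000043505), was at like levels in both libraries over all endothelial-like cells. Its level was 104.4 CPM in sph/+ and 103.6 CPM in sph/sph, from 4847 and 5316 UMIs, a ratio of 0.993 (0.955 to 1.03). In the 1 endothelial cluster with at least 25 cells of each library, it was at 47.0 CPM in sph/+ and 88.5 CPM in sph/sph. These levels came from 11 and 126 UMIs, a ratio of 1.89 (1.02 to 3.87). Because the allele is missense, the transcript level does not check the labels. Of the 8 GIMAP genes, which lie side by side on that chromosome, 6 were measured and 0 were 1.5-fold apart once 1 CPM was added to both levels. Their median log2 ratio was -0.23 at percentile 25.8 and ranged from -0.25 to -0.04 over the alternatives. The median in that cluster was 0.61 (0.171 to 1.001). Gimap8 had the lowest ratio, at -0.58, which lies at the 1.5-fold bound, followed by Gimap6 at -0.39 and Gimap4 at -0.31. Ptprc, which encodes the CD45 that the sort excluded, had 3 UMIs in sph/+ and 4 in sph/sph over all endothelial-like cells.

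Over 7470 measured genes, 822 were at least 2-fold higher in sph/sph and 788 at least 2-fold lower, and 274 and 116 were past 8-fold. The 2-fold counts ran from 516 to 1365 higher and from 557 to 1035 lower over the alternatives. Another 4507 genes lay within 1.5-fold, and the median log2 ratio of all measured genes was -0.07. The other genes with the lowest ratios were led by Aass, an enzyme of lysine breakdown, at -7.76, Dnase1l3, a secreted DNase, at -7.24, Enpep, an aminopeptidase of the angiotensin system, at -6.83, and Slc39a8, a zinc and manganese importer, at -6.27. The scavenger receptor Msr1 followed at -6.01, the mannose receptor Mrc1 at -5.99, the SLAM family receptor Cd84 at -5.91, the semaphorin receptor Plxnc1 at -5.71, the prostaglandin-degrading enzyme Hpgd at -5.70 and Oit3 at -5.65. Clec4g stood at -5.93 and Fcgr2b at -9.30.

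Genes with the highest ratios included much of the class II antigen presentation machinery. Cd74, the invariant chain, was at 2.26 CPM in sph/+ and 2518 CPM in sph/sph, 1114-fold higher (920 to 1362). The class II genes H2-Ab1, H2-Eb1 and H2-Aa had log2 ratios of 8.33, 7.95 and 7.74. Ubd, an interferon-induced ubiquitin-like modifier, had 0 UMIs in sph/+ and 998 CPM in sph/sph, at least 15458-fold higher against a floor of 3 UMIs over the library's endothelial-like cells. Sparcl1, a matricellular protein, had a log2 ratio of 9.35, Rgcc, a regulator of the cell cycle, 8.07, and Apln, the ligand of the apelin receptor, 7.85. Lpl, which encodes lipoprotein lipase, stood at 7.79, Tmem252 at 7.66 and Col18a1, the collagen that yields endostatin, at 7.61. The costimulatory receptor Tnfrsf9 had 1 UMI in sph/+ and 13626 in sph/sph, a ratio of 12333 with a counting interval from 2213 to 487144.

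**Figure D1:**
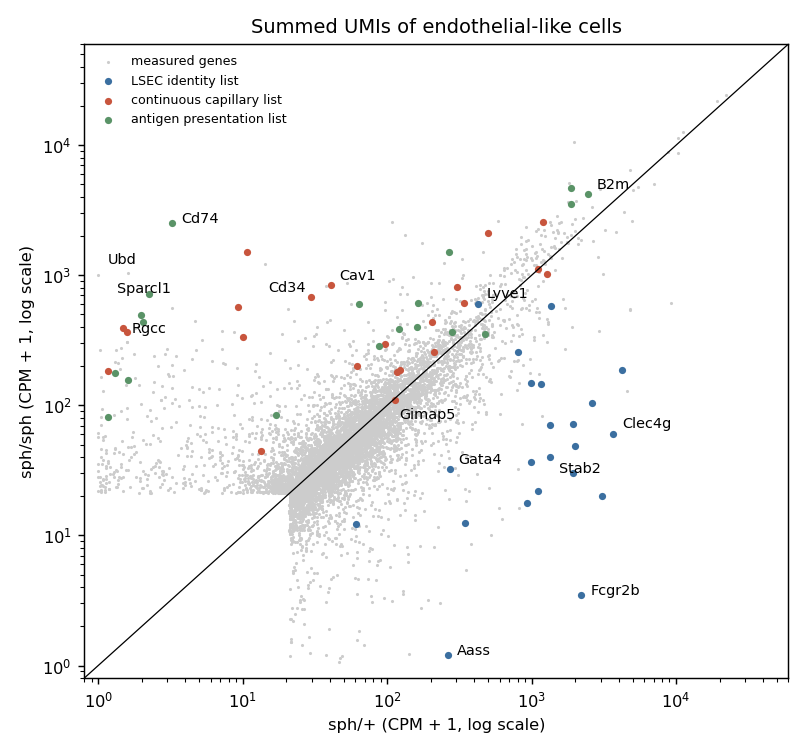
Summed expression of each measured gene in endothelial-like cells of the sph/+ library (horizontal) and the sph/sph library (vertical), as CPM plus 1 on log scales, with the line of equal levels. LSEC identity genes lie below the line except Lyve1, and most continuous capillary and antigen presentation genes lie above it.

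The LSEC identity list, which holds scavenger receptors, transcription factors and other genes of sinusoidal cells, had 22 measured members. Of these, 21 were at least 1.5-fold lower in sph/sph and 0 were higher, with a median log2 ratio of -4.74 at percentile 0.0. Stab1, the partner scavenger receptor of Stab2, was at -1.23, Stab2 at -5.05 and Maf, a sinusoidal transcription factor, at -4.66. Not all members were scarce in sph/sph, where Stab1 was still at 579 CPM, Flt4 at 258 CPM and F8 at 145 CPM. Lymphatic-like cells held 52.6% of the sph/sph Stab1 UMIs, and without these cells the Stab1 ratio was -1.94. Lyve1, a hyaluronan receptor of sinusoidal and lymphatic endothelium, was the exception at 0.52, but lymphatic-like cells held 95.7% of its sph/sph UMIs, and without these cells its ratio was -3.62. The Lyve1 ratio also turned to -0.41 when cells were weighted equally.

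The continuous capillary list had 22 measured members, of which 18 were at least 1.5-fold higher in sph/sph and 0 lower, with a median of 1.65 at percentile 100. After Rgcc and Apln its largest ratios were 7.29 for Aplnr, the apelin receptor, and 7.15 for Ly6c1, a surface antigen of capillaries. Cd34 stood at 4.51 and Cav1 at 4.36. Vwf, the clotting adhesion protein of large vessels, was at 61.1 CPM in sph/+ and 200 CPM in sph/sph, a log2 ratio of 1.69 that ranged from 1.52 to 2.81 over the alternatives. Its level was uneven among continuous vascular-like clusters. It was at 3347 CPM in one of 284 sph/sph and 2 sph/+ cells, and at 11.8 CPM in the largest, of 2841 sph/sph cells. The Vwf ratio is therefore not read as a change across capillary cells. Plvap, the protein of fenestral diaphragms, was at 0.29 over all endothelial-like cells. It was at -0.68 without the lymphatic-like cells, which held 60.4% of its sph/sph UMIs, and at -0.42 with cells weighted equally.

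Basement membrane and matrix genes were higher as a group, 15 of 22 against 2 lower, with a median of 1.79 at percentile 100. Besides Col18a1, the laminin chain Lamb1 stood at 7.59, fibronectin (Fn1) at 6.29 and nidogen (Nid2) at 4.96. Fn1 was among the top genes of the lymphatic-like cluster, so this class may carry much of the Fn1 ratio. That share was not measured. The endothelial to mesenchymal list had 8 measured members, 5 higher and 2 lower, with a median of 0.77 at percentile 98.6 that was 0.09 without a floor on members and 0.32 without the lymphatic-like cells. Its members went both ways, with Fn1 at 6.29, the matricellular gene Cyr61 at 3.49 and vimentin (Vim) at 2.08 against Twist1, a mesenchymal transcription factor, at -5.59.

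Antigen presentation genes were higher in 17 of 19 measured members and lower in 0, with a median of 2.31 at percentile 100. Interferon response genes were higher in 17 of 22 and lower in 0, with a median of 1.22 at percentile 100. The interferon-induced GTPase Igtp was at 4.45, Ifi27l2a at 4.41, Gbp2 at 4.05 and Gbp3 at 3.61. Ifi27l2a was among the 10 top genes of the lymphatic-like cluster, so this class may carry much of its ratio, and the share was not measured. Inflammatory adhesion genes and chemokines were higher in 10 of 15 and lower in 2, with a median of 1.74 at percentile 100 that was 0.96 without the lymphatic-like and cycling cells. Ccl2, which draws monocytes, was at 5.67, the acute phase protein Lcn2 at 5.32 and Ccl7 at 4.92. Cx3cl1 had 0 UMIs in sph/+ and 60.0 CPM in sph/sph, and with its ratio set at the bound of 3 UMIs the list's median was the same. Cxcl9, which draws T cells, was at 106 CPM in sph/+ and 2580 CPM in sph/sph. Ackr1, the venular chemokine receptor, was at -3.27.

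**Figure D2:**
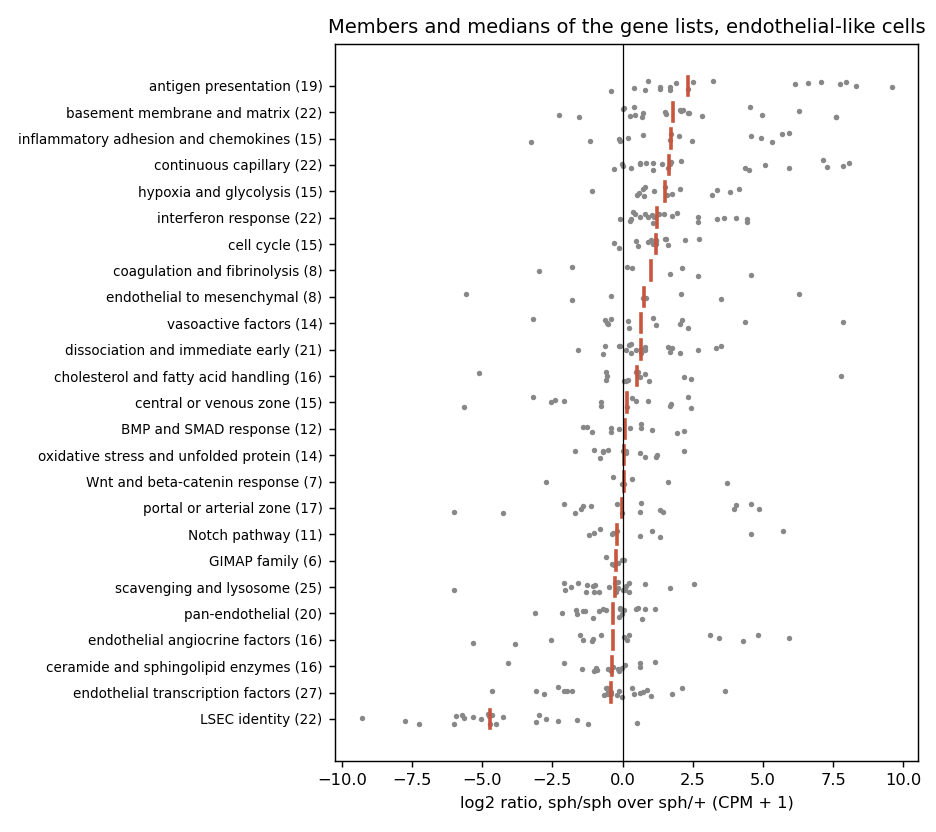
Median log2 ratio (sph/sph over sph/+) of the measured members of each gene list in endothelial-like cells, with the single members as points, the medians as red bars and the measured members in parentheses. The LSEC identity list lies at -4.74, and among these 25 lists, fixed in advance, the antigen presentation list has the highest median, 2.31.

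Hypoxia and glycolysis genes were higher in 13 of 15 and lower in 1, with a median of 1.53 at percentile 100. The hypoxia-induced gene Ankrd37 was at 4.16, the glucose transporter Slc2a1 at 3.83, Vegfa, the growth factor of endothelium, at 3.36 and the glycolytic activator Pfkfb3 at 3.18. Cell cycle genes were higher in 11 of 15 and lower in 0, with a median of 1.18 at percentile 100. The inhibitor Cdkn2a stood at 2.73, the nucleotide synthesis gene Tyms at 2.21, cyclin D1 (Ccnd1) at 1.60 and Ccnb2 at 1.53. Coagulation genes were higher in 4 of 8 and lower in 2, with a median of 1.01 at percentile 99.8 that was 1.69 at a floor of 5 CPM. The plasminogen activator Plat was at 4.59, factor VIII (F8) at -2.99, the protein C receptor Procr at 2.69 and Anxa2 at 2.12. Vasoactive factors were higher in 7 of 14 and lower in 2, with a median of 0.66 at percentile 99.7 that was 0.24 at a floor of 50 CPM and 1.08 at 5 CPM. The vasoconstrictor gene Edn1 was at 2.34 and the prostaglandin synthase Ptgs1 at -3.20.

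Lipid genes lay on both sides. The cholesterol and fatty acid handling list had 6 of 16 members higher and 3 lower, with a median of 0.50 at percentile 99.2. Besides Lpl, the fatty acid carrier Fabp4 was at 2.44 and the cholesterol exporter Abca1 at 2.20, while Apoe, an apolipoprotein, was at -5.13. Ceramide and sphingolipid enzymes were higher in 3 of 16 and lower in 6, with a median of -0.39 at percentile 4.06 that ranged from -0.90 to -0.15 over the alternatives. Sgpp1, a sphingosine phosphate phosphatase, was at -4.09, the desaturase Degs1 at -2.07, the ceramide synthase Cers4 at -1.46 and S1pr1, the sphingosine phosphate receptor, at 1.17.

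Endothelial transcription factors were higher in 7 of 27 and lower in 9, with a median of -0.41 at percentile 1.04. Maf stood at -4.66, Gata6 at 3.66, Gata4 at -3.07 and Meis1 at -2.80. The pan-endothelial list was higher in 3 of 20 and lower in 10, with a median of -0.35 at percentile 4.42 (-0.59 to -0.20 over the alternatives). The phosphatase Ptprb was at -3.13, the angiopoietin receptor Tek at -2.18, Calcrl at -1.68 and Clec14a at -1.64, while the adhesion genes Pecam1 and Cdh5 were at 0.54 and 0.49. Angiocrine factors, by which endothelium signals to hepatocytes and stellate cells, were higher in 5 of 16 and lower in 8, with a median of -0.36 at percentile 9.10. This median ranged from -0.76 to 0.12, so no direction is read for the list. The chemokine Cxcl12 was at 5.94, Bmp2, a regulator of iron balance, at -5.34, Igf1 at 4.83 and Pdgfb, a growth factor for pericytes, at 4.28. Scavenging and lysosome genes were higher in 3 of 25 and lower in 11, with a median of -0.26 at percentile 10.2 that reached -0.81 without the lymphatic-like cells. After Msr1, the lysosomal genes Lamp2 and Lgmn stood at -2.09 and -2.06 and Ctsh at 2.55.

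Lists of zones, of signalling pathways and of oxidative stress held members on both sides, and their medians changed sign among the alternatives, whose ranges follow in parentheses, so no direction is read for them. Portal or arterial genes were higher in 8 of 17 and lower in 7, with a median of -0.03 at percentile 56.8 (-0.66 to 0.62), and went from Msr1 at -6.01 and Ntn4 at -4.25 to Sema3g at 4.85 and Hey1 at 4.56. Central or venous genes were higher in 5 of 15 and lower in 7, with a median of 0.17 at percentile 84.5 (-0.77 to 0.36). The creatine synthesis gene Gatm was at -5.65, Ptgs1 at -3.20 and Wnt2, the pericentral Wnt ligand, at -2.55. Notch genes were higher in 5 of 11 and lower in 3, with a median of -0.20 at percentile 28.4 (-0.22 to 0.53) and the ligand Jag2 at 5.71. BMP and SMAD genes were higher in 5 of 12 and lower in 3, with a median of 0.08 at percentile 69.2 (-0.07 to 0.47), and Id1, a target of BMP signalling, at 1.94. Wnt response genes were higher in 2 of 7 and lower in 1, with a median of 0.05 at percentile 56.8 (-0.03 to 0.33), Myc at 3.71 and Nkd1 at -2.75. Oxidative stress and unfolded protein genes were higher in 5 of 14 and lower in 5, with a median of 0.06 at percentile 73.5 (-0.10 to 0.11).

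Measures of handling also differed between the libraries. Dissociation and immediate early genes were higher in 11 of 21 and lower in 3, with a median of 0.65 at percentile 99.98, and the heat shock gene Hspa1a at 3.33 and Atf3 at 3.49. The immediate early list took 0.575% of sph/+ and 0.733% of sph/sph UMIs in endothelial-like cells. Ribosomal protein genes took 8.33% and 11.3%, and mt- genes 6.07% and 5.56%.

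The cells themselves separated by library. Of 30 clusters, 27 drew over 95% of their cells from 1 library. LSEC-like cells were 9506 of the 10109 endothelial-like sph/+ cells, 94.0% (93.6 to 94.5), and 1 of the 10656 in sph/sph, 0.00938% (0.000238 to 0.0523). Continuous vascular-like cells were 45 in sph/+, 0.445% (0.325 to 0.595), and 8013 in sph/sph, 75.2% (74.4 to 76.0). The central-vein-like cluster of this class held 39 of the sph/+ and 231 of the sph/sph cells, so the class differs in make-up between the libraries. The sph/+ number depended on the clustering, with 21 cells at resolution 0.5 and 131 with each library clustered alone. Lymphatic-like cells, which carry the lymphatic regulator Prox1, were 8 in sph/+, 0.0791% (0.0342 to 0.156), and 1147 in sph/sph, 10.8% (10.2 to 11.4). Their name rests on detected markers, and the identity of the sph/sph cells is in doubt, since they also carried other transcripts given in the closing section. Cycling endothelial-like cells, led by Mki67, Top2a and other division genes, were 120 in sph/+, 1.19% (0.985 to 1.42), and 697 in sph/sph, 6.54% (6.08 to 7.03). Unnamed endothelial cells were 4.25% and 7.49%. The largest sph/+ part of these was a cluster of 346 cells with 10 LSEC and 10 continuous markers detected, Vwf at 900 CPM and Clec4g at 1070 CPM. The sph/sph part of these was nearly all 1 cluster of 797 cells, which held 53.1% of the Stab2, 63.4% of the Clec4g and 44.6% of the Gata4 UMIs of that library's endothelial-like cells. Named from 6 instead of 9 of the 12 markers, this cluster brought the LSEC-like share of sph/sph to 7.49%.

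**Figure D3:**
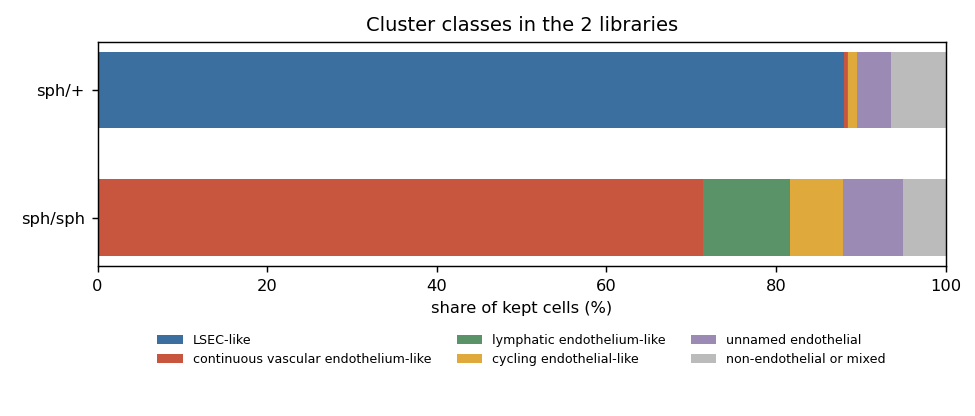
Share of kept cells (percent, horizontal) in each class, as stacked bars for the sph/+ and the sph/sph library. LSEC-like cells were 87.96% of kept cells in sph/+ and 0.00891% in sph/sph, where continuous vascular-like cells were 71.4%.

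**Figure D4:**
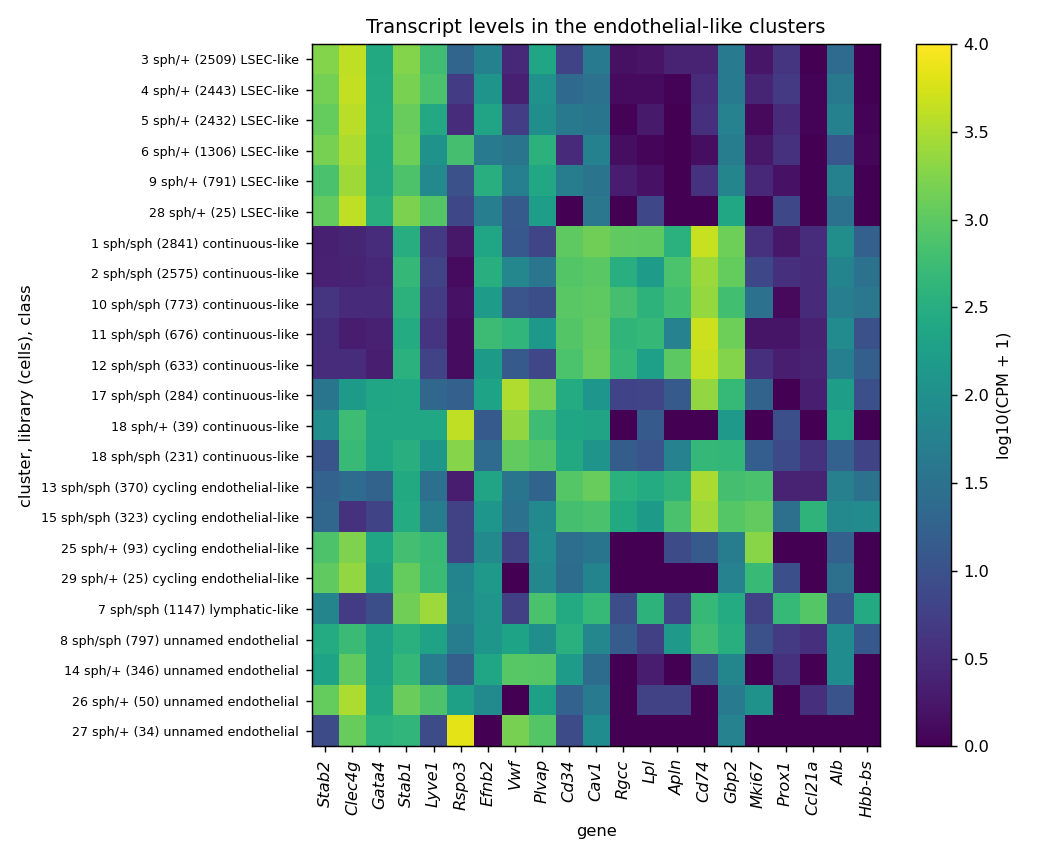
Transcript levels as log10 of CPM plus 1 (colour) of named genes in each endothelial-like cluster, split by library, with the cell number in parentheses. Stab2 and Clec4g were high in the LSEC-like clusters of sph/+, and Cd34 and Cd74 in most continuous vascular-like clusters of sph/sph.

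At an equal depth of 2000 UMIs per cell these genes also parted the libraries, in 9692 sph/+ and 9772 sph/sph endothelial-like cells. A Stab2 UMI was seen in 87.0% of sph/+ cells (86.3 to 87.7) and 4.60% of sph/sph cells (4.19 to 5.03). Clec4g was seen in 98.6% and 4.37%, Gata4 in 39.2% and 4.56%, and Cd34 in 4.77% and 70.8%. Ly6a, a surface antigen of arterial and capillary endothelium, was seen in 56.2% and 83.9%. Free RNA also gives such UMIs, so the shares were read in cells that should lack these genes as well. In 46 sph/sph hepatocyte-like cells, with a median of 2935 UMIs before thinning against 4153 in the endothelial-like cells thinned, Cd34 was seen in 23.9%, Ly6a in 50%, Clec4g in 4.35%, Gata4 in 2.17% and Stab2 in 0 cells. The intervals in these cells reached up to 7.71% for Stab2, 14.8% for Clec4g and 11.5% for Gata4, so these few cells do not show whether the sph/sph shares lie above free RNA. Planned as the free RNA level were all cells outside the endothelial classes, most of which can be mixtures with endothelial cells. In 430 such sph/sph cells Stab2 was seen in 2.33% (1.12 to 4.24), Clec4g in 1.86% (0.807 to 3.63) and Gata4 in 1.63% (0.657 to 3.33). These intervals lay below the endothelial-like shares. Cd34 was seen in 65.8% and Ly6a in 83.5% of those cells, and Stab2 in 76.4% of 682 such sph/+ cells. The transcripts were uneven among sph/sph endothelial cells, though. Clec4g was at 530 CPM, Stab2 at 292 CPM and Gata4 at 196 CPM in the unnamed ones. In continuous vascular-like cells they were at 30.9, 3.8 and 23.2 CPM, so the shares are not read as background alone. That class was uneven as well. Clec4g and Gata4 were at 495 and 223 CPM in its 231 central-vein-like sph/sph cells, and Gata4 at 225 CPM in its cluster led by Vwf. In its largest cluster, of 2841 sph/sph cells, Clec4g and Gata4 were at 1.56 and 2.25 CPM. Vwf was seen in 4.71% of sph/+ and 11.04% of sph/sph cells, and the interval in hepatocyte-like cells (0.531 to 14.8) holds the sph/sph share. The Vwf level was uneven among the sph/sph clusters, as given above, so this share is not read as free RNA alone. In 165 cholangiocyte-marked sph/+ cells, which can be mixtures and had a median of 10218 UMIs before thinning, Stab2 was seen in 37.6%, Clec4g in 45.5%, Gata4 in 10.3%, Ly6a in 30.9% and Cd34 in 1.21%. Lyve1 was seen in 37.8% and 12.5% of endothelial-like cells and Plvap in 29.8% and 13.8%, against their summed levels, so no order is read for either gene.

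**Figure D5:**
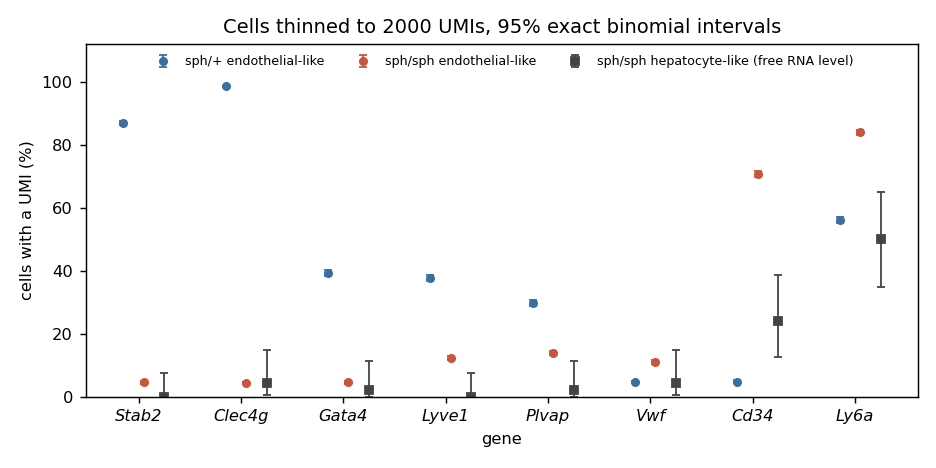
Share of endothelial-like cells (percent) with at least 1 UMI of each gene after thinning to 2000 UMIs, for the sph/+ and the sph/sph library, beside sph/sph hepatocyte-like cells as the free RNA level, with 95% exact intervals. Stab2 was seen in 87.0% and 4.60% of cells and Cd34 in 4.77% and 70.8%.

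Transcripts of other cell types in the endothelial-like cells were mostly low and differed in both directions. Hepatocyte genes summed to 122 CPM in sph/+ and 187 CPM in sph/sph, led by albumin (Alb) at 39.5 and 61.4. Erythroid genes were at 0.366 and 133 CPM, led by haemoglobin Hbb-bs at 80.7 in sph/sph, which was at 279 CPM in the lymphatic-like and 21.6 CPM in the continuous vascular-like cells. Stellate cell or fibroblast genes were at 162 and 422 CPM, and lymphatic-like cells held 97.9% of the sph/sph UMIs of Dcn, a collagen-binding proteoglycan. Macrophage genes were at 30.2 and 10.4 CPM, neutrophil genes at 0.215 and 3.0, T or NK cell genes at 0.366 and 3.25, platelet genes at 19.4 and 16.1, smooth muscle genes at 3.40 and 3.96, and cholangiocyte genes at 8.78 and 7.23. Some of these lists were carried by 1 or a pair of genes that endothelium can express. The dendritic cell list, at 1316 and 1665 CPM, was mostly Bst2. The B cell list, at 0.947 and 161 CPM, was mostly Ebf1, the plasma cell list, at 19.9 and 7.83, mostly Sdc1, the mesothelial list, at 6.76 and 49.4, mostly Gpm6a, and the progenitor list, at 356 and 126, Kit and Gata2.

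Among the kept cells outside the endothelial classes, several types came from 1 library. Cholangiocyte-marked cells were 167 in sph/+ and 0 in sph/sph, which allows a share of up to 0.0267%. Stellate or fibroblast-marked cells were 263 and 0, with the same limit. Macrophage-marked cells were 149 in sph/+, 1.38% of kept cells, and 25 in sph/sph, 0.223%.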

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

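The tests in this part were chosen only after the result was seen, except the one within the central-vein-like cluster. That one was written before its own result, but after the clusters, and so the choice of cluster, were known. With 1 mouse per genotype, none of these tests parts genotype from library. The first results stand out because they lie outside the comparison of endothelial-like cells and were above the sph/+ level beyond their counting intervals. Hepatocyte-like cells were 1.06% of kept sph/sph cells (0.880 to 1.27) and 0.111% of sph/+ cells (0.0574 to 0.194). Erythroid-marked cells were 0.9003% of kept sph/sph cells (0.734 to 1.09) and 0 of 10807 sph/+ cells, which allows a share of up to 0.0278%. Hepatocyte-marked endothelial mixtures were 2.83% in sph/sph (2.53 to 3.15) and 0.990% in sph/+ (0.812 to 1.20). Saa1, which encodes an acute phase protein of hepatocytes, was at 9817 CPM (9444 to 10202) in the 119 hepatocyte-like sph/sph cells and 311 CPM (181 to 497) in the 12 of sph/+. Barcodes over 15% mt- UMIs were 18% in sph/sph (17.4 to 18.6) and 5.71% in sph/+ (5.32 to 6.12).

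The low level of most LSEC transcripts in the sph/sph library was weighed first. A loss of LSECs at isolation or at the CD31 gate, with the other endothelial cells unchanged, would leave as many capillary cells per central-vein-like cell in both libraries, but that ratio was 410-fold higher in sph/sph (176 to 952), from 7782 and 231 cells against 6 and 73. With unnamed endothelial cells counted as capillary it was 6.74-fold higher (5.09 to 8.94), below the 10-fold difference set as the bound of this test but above the 3-fold one that the explanation allows. The first value rests on 6 sph/+ cells in a clustering that mostly parted the libraries. The number of sph/+ continuous vascular-like cells ran from 21 to 131 over the alternatives that recluster the cells, which the interval does not cover. The wider value lies between the 3-fold and the 10-fold bound. It counts as capillary 50 sph/+ cells of a cluster with 12 of 12 LSEC markers detected, and the 797 sph/sph cells of the cluster with 8. It therefore does not part LSECs from capillary cells. The test therefore does not decide whether LSECs were lost with the other endothelial cells unchanged. Barcodes left out for their mt- share carried Stab2 at 215 CPM in sph/sph against 41.6 CPM in kept endothelial-like cells, and Clec4g at 125 against 63 CPM. Their cell types were not set, and the unnamed sph/sph cluster of 797 cells carried these genes at 293 and 530 CPM. With the mt- limit at 25%, 2 sph/sph cells were LSEC-like. These barcodes do not show whether LSECs were lost. Hepatocyte transcripts in the sph/sph endothelial-like cells were 1.54 times the sph/+ level (1.49 to 1.59), which argues against another organ as the source of that library. A Stab2 UMI was seen in 4.60% of sph/sph and 87.0% of sph/+ cells at equal depth, which argues against shallower cells. An effect of the genotype, a difference between the libraries, and a loss of LSECs together with changes in the other cells stay open and untested.

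The 1147 lymphatic-like sph/sph cells, whose identity is in doubt, had a median of 9656 UMIs, against 3618 in continuous vascular-like cells, so doublets were weighed. Doublets with the continuous vascular-like cells rich in Rgcc would carry it, but its level in lymphatic-like cells was 1.32% of that in continuous vascular-like cells. This argues against doublets with those cells. Rgcc was at 5.35 CPM in the continuous vascular-like cluster led by Vwf and 12.1 CPM in the central-vein-like one, so doublets with these are not covered. Doublets with erythroid or stellate cells were not tested. More hilar or capsular tissue in the sph/sph sample could bring lymphatic vessels along, and would bring cholangiocytes and mesothelial cells. Cells with these markers were 185 in sph/+, 1.71% (1.48 to 1.97), and 0 in sph/sph, but the CD31 gate should remove both types and the other stellate-marked cells were skewed alike, 245 against 0, so this explanation stays open. An effect of the genotype on lymphatic-like cells was not tested and stays open.

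Antigen presentation and interferon transcripts were higher in sph/sph. Immune cells or their free RNA would bring their own abundant transcripts, but Cd79a, Cd79b, Lyz2, C1qa and Ptprc together reached 0.156% of the Cd74 level in sph/sph endothelial-like cells, which argues against them. A change of cell types alone would leave the shared central-vein-like cluster, 39 cells in sph/+ and 231 in sph/sph, with like levels, but there the antigen presentation list had a median log2 ratio of 2.02 (1.78 to 2.29). The cells of this cluster need not be of matched type, since Rspo3 and Stab2 also differed there. A further 34 sph/+ cells with Rspo3 and Wnt9b among their top genes clustered apart and are not counted in it. Free RNA could add to the difference. Relative to all sph/sph endothelial-like cells, Igtp stood in these cells at 92.9%, H2-Ab1 at 46.8% and Cd74 at 18.4%, while Rgcc stood at 3.56% and Sparcl1 at 3.50%. Cxcl9 at 5.53% and Ubd at 2.74% lay near the latter pair, so free RNA stays open for these genes. An interferon-type response across endothelial types in the sph/sph mouse may be a candidate explanation, and a difference between the animals or libraries apart from genotype cannot be excluded.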

How the results depend on the processing

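Of 25 list medians, 12 were at least 1.5-fold from 0 difference, and 0 of these changed sign under the 17 alternatives that recompute them. Of 35 named genes the same held for 30. These were the genes with the highest and lowest ratios and those named whatever their values, except Ptprc. Other list members named for their ratio were not recomputed as single genes. The sign changed for 7 lists (portal, central, Notch, BMP, Wnt, oxidative stress and angiocrine) and for Gimap5, Lyve1 and Plvap, all within 1.5-fold. Of 425 list values 145 left their counting interval, as did 228 of 578 values of named genes other than Gimap5. Of the 12 lists, 4 moved by over 1.5 times, and those within 1.5-fold have their range beside the result if it moved as far. The endothelial to mesenchymal median of 0.774 was 0.089 without a floor, 0.324 without the lymphatic-like cells and 0.372 without these and the cycling cells, where the inflammatory median of 1.735 was 0.962. The vasoactive median of 0.663 was 1.083 at a floor of 5 CPM and 0.243 at 50 CPM, and the coagulation median of 1.012 was 1.694 at 5 CPM. Over the alternatives that recompute them, LSEC-like cells were 85.2% to 97.0% of endothelial-like cells in sph/+ and 0% to 7.49% in sph/sph, genes at least 2-fold higher numbered 516 to 1365, and genes lower 557 to 1035. For the shares, the counts of genes, the LSEC identity and continuous capillary lists and Gimap5, the values that left their counting interval, or for counts 1.5 times the reported one, follow by setting. Their cause was not tested unless given. At most 10% mt- UMIs gave an LSEC-like share of 93.2% and endothelial-like shares of 89.3% in sph/+ and 94.1% in sph/sph, with medians of -4.81 for the LSEC identity and 1.58 for the continuous capillary list. At most 25% gave 97.0% and 88.3% in sph/+, with medians of -4.68 and 1.91. At least 1000 genes and 2000 UMIs gave 93.2% and 91.9% in sph/+. Without doublet removal the sph/+ shares were 93.03% and 89.85%, and the capillary median 1.60. Resolution 0.5 gave 97.0% and 84.2% in sph/+, a capillary median of 2.06 and a Gimap5 log2 ratio of -0.069. Resolution 2.0 gave 93.3% and 88.5% in sph/+, and 0% and 94.5% in sph/sph. Clustering each library alone gave LSEC-like shares of 85.2% and 0%. With cells weighted equally the medians were -4.89 and 1.73, and with 5 CPM added before the ratio -4.60 and 1.52. Floors of 5 and 50 CPM gave 1365 and 516 genes at least 2-fold higher, because the floor sets how many genes are measured. The following settings were added after seeing the data. Clustering without the endothelial list genes gave 93.5% and 92.98% in sph/+ and an endothelial-like share of 94.3% in sph/sph. Without the lymphatic-like cells the medians were -4.80 and 1.87, and without these and the cycling cells the capillary median was 1.84 and the Gimap5 log2 ratio 0.062. Naming LSEC-like clusters from 6 of 12 markers brought the sph/sph share to 7.49%, the share of the unnamed cluster it admits. Keeping hepatocyte-marked clusters gave 93.1% and 94.5% in sph/+ and an endothelial-like share of 97.8% in sph/sph. A planned median over clusters with at least 50 cells of each library was not run, since 0 endothelial clusters had them. Depth limits genes below 20 CPM, and 1 mouse per genotype limits every value.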

Other observations

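The test of organ lists in this part was chosen only after the result was seen, as were the genes named here. A central-vein-like cluster, marked by the Wnt enhancer Rspo3 and the ligand Wnt9b, was the only endothelial cluster with at least 25 cells of each library. Another cluster led by these genes held 34 sph/+ and 0 sph/sph cells and is not part of the comparison. It had Rspo3 at 6951 CPM, Clec4g at 1154 CPM, Gata4 at 360 CPM and Stab2 at 7.35 CPM. In the shared cluster Rspo3 was at 4141 CPM in sph/+ and 1885 CPM in sph/sph, and Wnt9b at 730 and 533 CPM. Clec4g, at 581 and 495 CPM, and Gata4, at 252 and 223 CPM, had ratios whose counting intervals included 1 there. Stab2 was at 89.7 CPM and 9.84 CPM, and Vwf at 2237 and 1079 CPM. The interferon response list had a median log2 ratio of 1.48 in these cells (1.12 to 1.82) and the inflammatory list one of 1.76 (1.30 to 2.55). Other lists were higher there too. The cell cycle list, with 7 measured members, was at 2.45 (1.28 to 3.17). The Wnt response list, with 8, was at 1.38 (0.79 to 2.22). With so few members and 234240 sph/+ UMIs in the cluster, the size of these 2 medians is uncertain beyond their intervals. The dissociation list, a measure of handling, was at 0.57 (0.43 to 0.80). The coagulation list was at 0.96 (0.30 to 1.21) and the basement membrane list at 0.58 (0.27 to 0.96). Endothelial transcription factors were at 0.55 (0.14 to 0.70), with 13 members higher and 6 lower, opposite in sign to the -0.41 over all endothelial-like cells. The LSEC identity list had a median of -0.16 (-0.30 to 0.09) in this cluster, with 6 of 22 members higher and 7 lower, against -4.74 over all endothelial-like cells. The endothelial to mesenchymal list was at -0.65 (-0.89 to -0.39), the portal or arterial list at -0.64 (-0.97 to -0.17) and the central or venous list at -0.45 (-0.58 to -0.26).

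The lymphatic-like cells of the 2 libraries differed in their lymphatic transcripts. Ccl21a, the chemokine that draws dendritic cells into lymph vessels, was at 8991 CPM in the 8 sph/+ cells and 876 CPM in the 1147 sph/sph cells, and Prox1 at 809 and 481 CPM. Mmrn1 was at 5071 and 1183 CPM and Pdpn at 467 and 40.3 CPM. The sph/sph cells also carried Cd34 at 281 CPM, so whether they are lymphatic endothelium is in doubt. Hamp, which encodes the iron-regulating hormone hepcidin, was at 393 CPM in the sph/sph lymphatic-like cells, which held 98.2% of the Hamp UMIs of that library's endothelial-like cells, while Alb was at 11.3 CPM there. Hamp was at 772 CPM in 25 macrophage-marked sph/sph cells and 275 CPM in hepatocyte-like ones. In sph/+, a small LSEC-like cluster of 25 cells was led by the interferon-induced genes Cxcl10, Rsad2 and Ifit1.

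Over all endothelial-like cells, whichever class they were named, the LSEC identity list gave at 2000 UMIs per cell a median of 69 UMIs in sph/+ and 2 in sph/sph, and the continuous capillary list 10 and 28. In 46 sph/sph hepatocyte-like cells the medians were 0 and 2 UMIs. In clusters outside the endothelial classes, most of which can be mixtures with endothelial cells, they were 63 and 8 in sph/+ and 1 and 27 in sph/sph. At least 20 LSEC-list UMIs were found in 96.7% of sph/+ cells (96.4 to 97.1) and 2.91% of sph/sph cells (2.58 to 3.26), with 175 and 604 cells between 15 and 24. Among the barcodes left out for their mt- share, Stab2 was at 1481 CPM of non-mt UMIs in sph/+ and 215 CPM in sph/sph, against 1419 and 41.6 CPM in the kept endothelial-like cells. Over all deposited barcodes Stab2 was at 1279 and 43.9 CPM.

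Several genes with high sph/sph levels, such as Lpl, Fabp4, Meox2 and Tcf15, are known from capillaries of heart and adipose tissue, which take up fatty acids. A list of such genes, written after the values were seen, was higher in 8 of 11 measured members and lower in 1, with a median log2 ratio of 4.33. Kidney capillary genes were higher in 5 of 9 and lower in 2, with a median of 1.72, brain capillary genes in 2 of 4 and 0, with 2.02, and lung capillary genes in 2 of 5 and 3, with -0.84. A general increase of capillary genes of all organs would put these medians close together, and the smallest gap below the heart and adipose list was 2.31. With 4 brain and 5 lung genes measured, and a list built from genes already seen to be high, the test leaves open whether the sph/sph capillaries may resemble those of a fatty acid-using organ.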
